A study of Homo sapiens with 10 samples.

How the data were processed

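RNA of 5 uterine fibroid and 5 normal myometrium samples was measured on oligonucleotide arrays, each sample on 1 array. Per the labels, tissue was placed in a preservative at most 30 minutes after surgery and kept at -20 C. The deposited table holds the authors' linear signal intensity for 22283 probe sets on each array. The mean after trimming 2% of the values from each end was 125.03 to 125.05 on all 10 arrays, so the deposited intensity values were already scaled to a shared mean; the software and its detection calls are not given in the sources used here. Median signals were 47.7 to 62.7.

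Because the trimmed means lay within 1.5 times of one another, the values were not rescaled. Signals under the pooled 20th percentile of all non-control values (12.4) were set to it, and log2 was taken. The 68 control probe sets were left out of the tests. Of the others, 19071 had 1 gene symbol, 1043 several and 2107 none; only the first kind were used, and 19059 of their symbols were matched through the gene ID to the RefSeq table of GRCh38.p14, used for names only. They gave 11963 symbols. A gene was represented by its probe set with the highest mean log2 value over the 10 arrays, and probe sets whose mean lay under the pooled 40th percentile (38.4) were left out, leaving 7848 genes. Of these, 286 had at least 1 value at the floor. No coordinates are given, since the arrays carry none.

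Fibroid was compared with myometrium by limma 3.58.1 (lmFit and eBayes with a variance trend, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The labels do not say that a shared title number means a shared donor, so the 2 pairs of fibroid arrays with the same number entered as a random block (duplicateCorrelation, statmod 1.5.0). Deviations from the fibroid mean correlated at 0.200 and 0.175 across genes within these pairs and at -0.464 to -0.200 in the 8 other pairs, and the estimated correlation was 0.607. Fitted log2 fold changes weight these arrays together, so they differ slightly from the difference of group means. Whether other samples came from separate donors is not stated beyond their numbers, and p-values measure the spread between these samples. No 2 arrays were copies: at most 0.431% of values were equal. Fits that leave out arrays keep the correlation of 0.607, since few pairs remain to estimate it.

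The groups, the fit, 32 gene lists (20 of pathways or gene families and 12 of cell type markers), the rule for named genes and most alternatives were chosen before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with no overlap between groups, up to 4 members of each list with the smallest p, and every passing gene of the list often reported in fibroids; FOSB and a few others in the closing section were chosen after their values were seen. Lists were tested with cameraPR at a preset correlation of 0.01 between members, with Benjamini-Hochberg adjustment over the 28 lists that had at least 5 tested members. Markers of blood cells, nerve, adipocytes and mesothelium had fewer and were not tested. With a correlation estimated from the arrays, 0 of the 14 calls held; fry, which asks whether a list's genes move one way without setting them against other genes, called 6 in one direction and 18 for change in either direction. A list score is the mean over members of the log2 signal minus the myometrium mean.

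RNA quality was read from the 3' to 5' control ratios of GAPDH and beta-actin, compared by exact two-sided permutation tests. The pipeline was tested on simulated data for this comparison: of 200 genes changed among 7848, 47% of 2-fold and 87% of 4-fold changes were called, 9 of 143 calls were false, and with no change simulated 0 genes were called. Simulated genes were independent of one another, with normal errors and a correlation of 0.6 within same-numbered pairs, as the model assumes. Measured genes are correlated, so these figures test the code and do not give the power or false calls in the measured data. Alternatives covered the block, normalization, the treatment of low values, the filter, the variance model, the probe set per gene, the test, each array left out, each same-numbered pair left out and covariates for RNA quality. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.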

Results

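Gene expression was measured in uterine fibroid (leiomyoma, a benign tumour of the smooth muscle of the uterus) and in normal myometrium, the muscle layer of the uterus, on human oligonucleotide arrays. There were 5 arrays of each tissue, and each array gave 1 signal per probe set for 22283 probe sets. The median signal of an array lay between 47.7 and 62.7. The 5 fibroid arrays carried 3 different numbers in their titles, since fibroids 2 and 3 shared one and fibroids 4 and 5 another, while the 5 myometrium arrays carried 5 numbers, none of them a fibroid's. The labels therefore pair no fibroid with a myometrium array. They do not say whether different numbers mean different donors, so differences between donors cannot be set apart from those between tissues. The number of arrays limits the precision of every value below.

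The comparison asks which genes differ in expression between fibroid and normal myometrium. Fibroids had far more transcript of the glutamate receptor subunit GRIA2, the calmodulin-binding peptide PCP4, cardiac alpha-actin ACTC1, the imprinted gene MEST and the secreted Wnt antagonist SFRP1. They had far less of the transcription factors FOS, ATF3, KLF4 and NR4A1, of the matricellular protein CCN5 and of the mast cell protease TPSAB1. Markers of endothelial cells and mast cells and the immediate early genes were lower as groups in a test with a preset correlation. The genes often reported as changed in fibroids, of which 8 rose and 5 fell, leaned upward in that test. That list mixes genes reported in either direction, so its lean depends on how many of each kind it holds. With an estimated correlation none of these groups passed: adjusted p = 0.15 for endothelial cells and for mast cells, adjusted p = 0.172 for immediate early genes and adjusted p = 0.206 for the often reported genes. The fry test, which does not set a list against other genes, called each of them in the same direction. Its adjusted p = 0.00475 for endothelial and for mast cells and 0.0174 for each of the others. It also called the lists of retinoic acid genes and of interferon response (fry adjusted p = 0.025 for each). Of 7848 genes tested with limma, 160 passed an adjusted p of 0.05, 72 of them higher and 88 lower in fibroid, and 136 differed by at least 2-fold. The folds ranged from 1.61 to 27.6, with a median of 2.71. In 149 of the 160 the values of the 5 fibroids and the 5 myometrium arrays did not overlap, as in 500 of all 7848 genes (6.37%). Chance gives 0.794% for independent arrays, and 1 of the 26 splits that keep same-numbered arrays together is 3.85%.

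GRIA2 rose most, by 4.79 ± 0.78 on the log2 scale (SE, adjusted p = 0.00793). Its log2 signal was 9.78 ± 0.66 (SD, n = 5) in fibroid and 4.91 ± 1.86 (SD, n = 5) in myometrium, where 3 of the 5 arrays lay at the floor, so the fold depends on that floor: the value was 5.97 with the floor at the 5th percentile. It was 5.49 without myometrium 2, whose log2 signal was the highest of its group. PCP4 rose by 3.11 ± 0.57 (SE), from 9.10 ± 1.41 to 12.27 ± 0.36 (SD, n = 5 each), and ACTC1 by 3.01 ± 0.56 (SE; 2.37 without fibroids 2 and 3). MEST was 5.66-fold higher (adjusted p = 0.00332), with a log2 signal that rose from 7.64 ± 0.72 to 10.07 ± 0.41 (SD, n = 5 each). COPG2IT1, a non-coding transcript from the locus next to MEST, rose by 2.47 ± 0.33 (SE). SFRP1 rose by 2.23 ± 0.28 (SE, adjusted p = 0.00276), from 9.25 ± 0.37 to 11.42 ± 0.41 (SD, n = 5 each). The neurokinin receptor gene TACR2 rose by 2.44 ± 0.44 and the recombination gene RAD51B by 2.22 ± 0.40 (SE). PAGE4 and CCN6 rose by 2.47 ± 0.54 and 2.39 ± 0.51 (SE), but their calls held in only 3 and 6 of the 10 fits that left out 1 array. With same-numbered arrays averaged the calls of PCP4 and PAGE4 were lost, as were that of CCN6 with the first array of each pair and that of PAGE4 with the second. MEST, COPG2IT1 and SFRP1 passed with either same-numbered pair left out, while each of the other genes named here lost its call without at least 1 of the pairs.

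FOS fell by 3.51 ± 0.68 on the log2 scale (SE, adjusted p = 0.0174), from 11.14 ± 1.39 in myometrium to 7.45 ± 1.02 in fibroid (SD, n = 5 each), and the value was -4.11 without fibroid 1. ATF3, a stress-induced transcription factor, fell by 3.42 ± 0.54 (SE, adjusted p = 0.00745), and CCN5 fell by 3.29 ± 0.54 (SE), with 2 of the 5 fibroid arrays at the floor and the others at a log2 signal of 4.04 to 4.19, so the size of that fall depends on the floor (-2.67 with a pseudocount in its place). CYBRD1, a ferric reductase, fell by 3.26 ± 0.61 (SE), with 3 of the 5 fibroid arrays at the floor; fibroid 1 had a log2 signal of 7.19 against 3.63 to 3.70 in the other fibroids, and without it the value was -4.28, while it was -4.08 with the floor at the 5th percentile. The mRNA decay factor ZFP36 fell by 2.94 ± 0.53, KLF4 fell by 2.87 ± 0.46 and the lipid transporter gene ABCA8 fell by 2.74 ± 0.52 (SE). The cytoskeletal linker PPL, with 3 of the 5 fibroid arrays at the floor and a call lost with the floor at the 5th percentile, fell by 2.80 ± 0.57 and the nuclear receptor NR4A1 fell by 2.75 ± 0.62 (SE), with calls that held in 8 and 3 of the 10 fits that left out 1 array. The tryptase TPSAB1 fell by 2.45 ± 0.45 (SE, adjusted p = 0.0127). With same-numbered arrays averaged the calls of FOS, CYBRD1, ZFP36 and NR4A1 were lost, and that of FOS also with the first array of each pair. With the second array of each pair those of CYBRD1, NR4A1 and TPSAB1 were lost. Every gene of this paragraph lost its call without at least 1 of the same-numbered pairs.

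**Figure D1:**
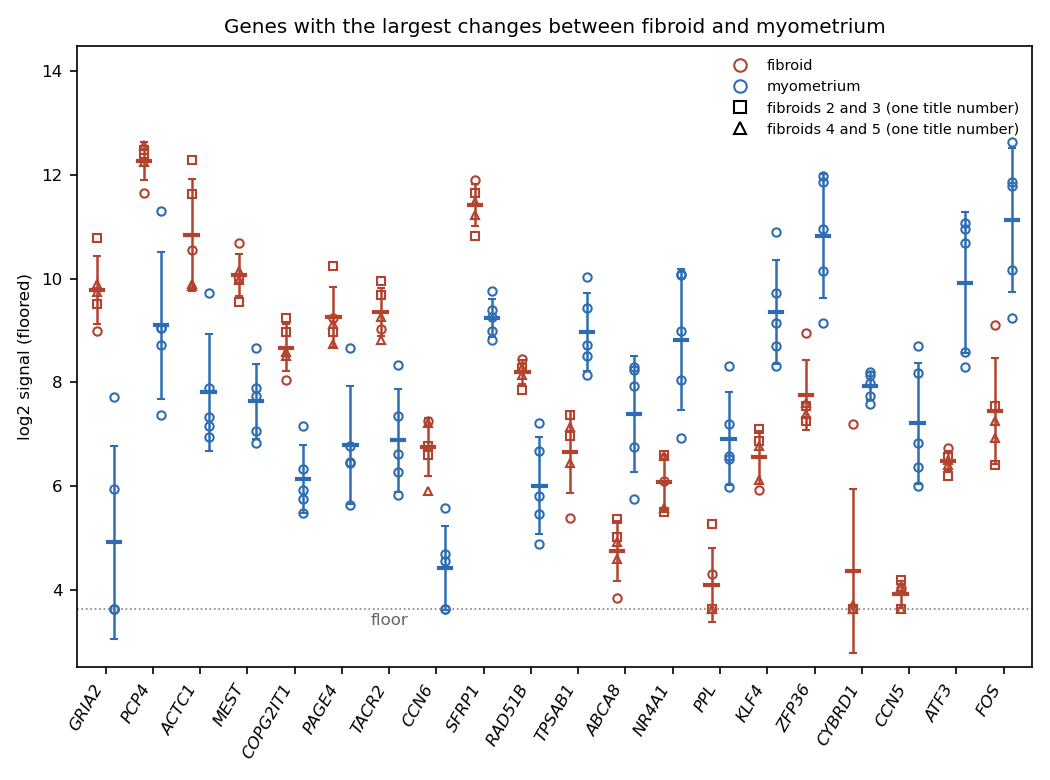
Log2 signal, floored, of the 10 genes with the largest rise and the 10 with the largest fall in fibroid among the passing genes picked for having no overlap between the groups, 1 point per array, with group means (thick bars) and SD (thin bars) over 5 fibroid (red) and 5 myometrium (blue) arrays; squares and triangles mark fibroids that share a title number. For GRIA2, 3 of the 5 myometrium arrays lie at the floor, and for CYBRD1 and PPL 3 of the 5 fibroid arrays do.

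Immediate early genes, which cells transcribe within minutes of a stimulus, were lower in fibroid as a group. Of 24 members tested, 11 fell and 13 did not pass, 23 had a negative log2 fold change, and the median was -1.84 (cameraPR, adjusted p = 2.8e-29). That test assumes a small correlation between members; with an estimated correlation the group's adjusted p = 0.172. Adjusted over the list alone, 22 fell. The shear-responsive factor KLF2 fell by 2.05 ± 0.34 and EGR1 fell by 1.89 ± 0.33 (SE), beside FOS, ATF3, ZFP36, KLF4 and NR4A1. FOSB, named after its value was seen, had the largest fall of all passing genes, since it fell by 4.35 ± 1.05 (SE, adjusted p = 0.0498), but its groups overlapped and 3 of the 5 fibroid arrays lay at the floor. The group's mean log2 difference from myometrium was -2.04 ± 0.39 in fibroid (SD, n = 5), below every myometrium array in 5 of 5 fibroids, but the myometrium arrays themselves spread by 0.885 (SD, n = 5).

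Endothelial markers were lower in fibroid. All 20 tested had a negative log2 fold change, with a median of -0.83 (adjusted p = 3.3e-15), and 3 passed alone. With an estimated correlation the group's adjusted p = 0.15. The endothelial sialomucin EMCN fell by 2.12 ± 0.32 (SE, adjusted p = 0.0055), the venular chemokine receptor ACKR1 fell by 1.93 ± 0.32 (SE) and the VEGF receptor KDR fell by 1.29 ± 0.28 (SE, past in 3 of the 10 fits without 1 array). Adjusted over the list alone, 14 fell. CDH5 differed by -1.23 ± 0.32 (SE) and did not pass. Mast cell markers were lower too: all 7 tested were negative, with a median of -1.73 (adjusted p = 5.1e-13, and adjusted p = 0.15 with an estimated correlation), and 4 fell, or 6 adjusted over the list alone. GATA2, a transcription factor of mast cells that endothelium also expresses, fell by 1.73 ± 0.23 (SE), and the protease CPA3 fell by 2.01 ± 0.44 and TPSB2 fell by 1.96 ± 0.44 (SE), past in 5 and 3 of the 10 fits without 1 array. With same-numbered arrays averaged the calls of KDR, CPA3 and TPSB2 were lost, and CPA3 was at -1.38 without fibroid 1. All 5 fibroids lay below all 5 myometrium arrays for the mean of either marker group.

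Genes often reported as changed in fibroids, a list that holds genes reported in either direction, leaned upward: 8 rose, 5 fell and 16 did not pass, with a median of 0.87 over 29 members (adjusted p = 0.000513; adjusted p = 0.206 with an estimated correlation). No reported direction was fixed for each gene, so this lean depends on how many of each kind the list holds. It does not say whether the genes moved as reported. Adjusted over the list alone, 12 rose and 8 fell. Besides GRIA2, PCP4, MEST, SFRP1 and RAD51B, the p53 target ZMAT3 rose by 1.88 ± 0.22 (SE, adjusted p = 0.0016), the kinesin KIF5C by 2.14 ± 0.42 and the microtubule-binding doublecortin DCX by 2.56 ± 0.58 (SE). DCX passed in only 2 of the 10 fits without 1 array, and the calls of KIF5C and DCX were lost with same-numbered arrays averaged and with either array of each pair alone. ALDH1A1 fell by 2.34 ± 0.40 and the calcitonin receptor-like gene CALCRL fell by 1.99 ± 0.47 (SE), the latter past in 3 of those 10 fits. The matricellular CCN1 fell from 11.15 ± 0.77 to 9.06 ± 0.47 (log2 signal, SD, n = 5 each). Genes of retinoic acid synthesis, binding and response, to which ALDH1A1 also belongs, had a median of -0.52 over 14 members (adjusted p = 0.00699; adjusted p = 0.15 with an estimated correlation); 1 fell, and adjusted over the list alone 2 rose and 6 fell. The retinoic acid-binding CRABP2 was at 2.22 ± 0.58 (SE, adjusted p = 0.0697) and did not pass.

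Collagens were higher as a group, with a median of 0.74 over 18 members (adjusted p = 0.00107; adjusted p = 0.357 with an estimated correlation), but 0 passed alone in limma, and 6 rose adjusted over the list alone. COL5A2 stood at 1.17 ± 0.28 and COL4A5 at 1.23 ± 0.31 (SE). The proteoglycans and matrix glycoproteins went both ways: fibronectin FN1 rose by 1.16 ± 0.22, while EFEMP1 fell by 2.20 ± 0.31, FBLN2 fell by 1.87 ± 0.42 and FBLN1 fell by 1.31 ± 0.31 (SE). FBLN2 and FBLN1 passed in 5 and 3 of the 10 fits without 1 array. The 32 members together had a median of 0.28 and a mean of 0.0029 (adjusted p = 0.978), and 4 rose and 4 fell adjusted over the list alone. Matrix proteases, their inhibitors and crosslinking enzymes had a median of -0.06 and a mean of 0.024 over 21 members (adjusted p = 0.386), with MMP11 at 2.79 ± 0.77 (SE, adjusted p = 0.0853) not past. Fibroblast markers were lower, with a median of -0.67 over 16 members (adjusted p = 0.00825; adjusted p = 0.236 with an estimated correlation). In that list GSN fell by 0.90 ± 0.21 (SE, past in 2 of the 10 fits), beside FBLN1, and SFRP4 rose by 1.64 ± 0.30 (SE). With same-numbered arrays averaged the calls of FBLN1 and GSN were lost. The group's call was lost without fibroids 4 and 5 (median -0.43) and with the beta-actin RNA quality ratio as a covariate (median -0.54).

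Proliferation genes were higher as a group, with a median of 0.31 over 11 members (adjusted p = 0.0019; adjusted p = 0.236 with an estimated correlation). The thymidylate synthase TYMS rose by 1.78 ± 0.28 (SE, adjusted p = 0.00648) and the replication clamp PCNA by 0.98 ± 0.19 (SE), while MCM2 was at 0.73 ± 0.28 (SE) and did not pass. With the beta-actin ratio as a covariate the group's call was lost, with a median of -0.04, and so were those of TYMS at 1.65 and PCNA at 0.91. The other 3 groups past the test on the higher side held 0 genes past limma's threshold. Cytosolic ribosomal proteins had a median of 0.25 over 26 members (adjusted p = 0.00144), the smooth muscle contractile apparatus one of 0.18 over 21 (adjusted p = 0.00477) and oxidative phosphorylation one of 0.23 over 24 (adjusted p = 0.011). With an estimated correlation the adjusted p = 0.428 for each of these 3. They also missed the threshold after quantile normalization, with medians of 0.07, 0.10 and 0.18, in the same direction. The ribosomal call was also lost with the beta-actin ratio as a covariate (median 0.06). Without myometrium 1 the contractile call was lost (median 0.08), and the oxidative one was lost without fibroid 1 (0.17) and without myometrium 1 (0.13). Adjusted over the list alone 3 contractile genes rose, among them the calcium-binding CASQ2 at 1.57 ± 0.40 (SE).

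On the lower side, interferon response and antigen presentation had a median of -0.31 over 24 members (adjusted p = 0.00256; adjusted p = 0.172 with an estimated correlation), with IFI27 at -0.81 ± 0.22 (SE) and 0 members past limma's threshold. Prostaglandin and oxytocin signalling and gap junction genes had a median of -0.44 over 15 (adjusted p = 0.0197; adjusted p = 0.172 with an estimated correlation), with the endothelin receptor EDNRB at -1.40 ± 0.35 (SE). That call was lost with the beta-actin ratio as a covariate (median -0.39), without fibroids 4 and 5 (-0.45) and with the filter at the 60th percentile (-0.31). Epithelial markers had a median of -0.61 over 6 (adjusted p = 0.0152; adjusted p = 0.428 with an estimated correlation), with KRT18 at -1.57 ± 0.39 (SE); without myometrium 2, the highest array, the median was -0.27 and the call was lost, as it was without fibroid 1 (-0.59) and with the GAPDH ratio as a covariate (-0.47).

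**Figure D2:**
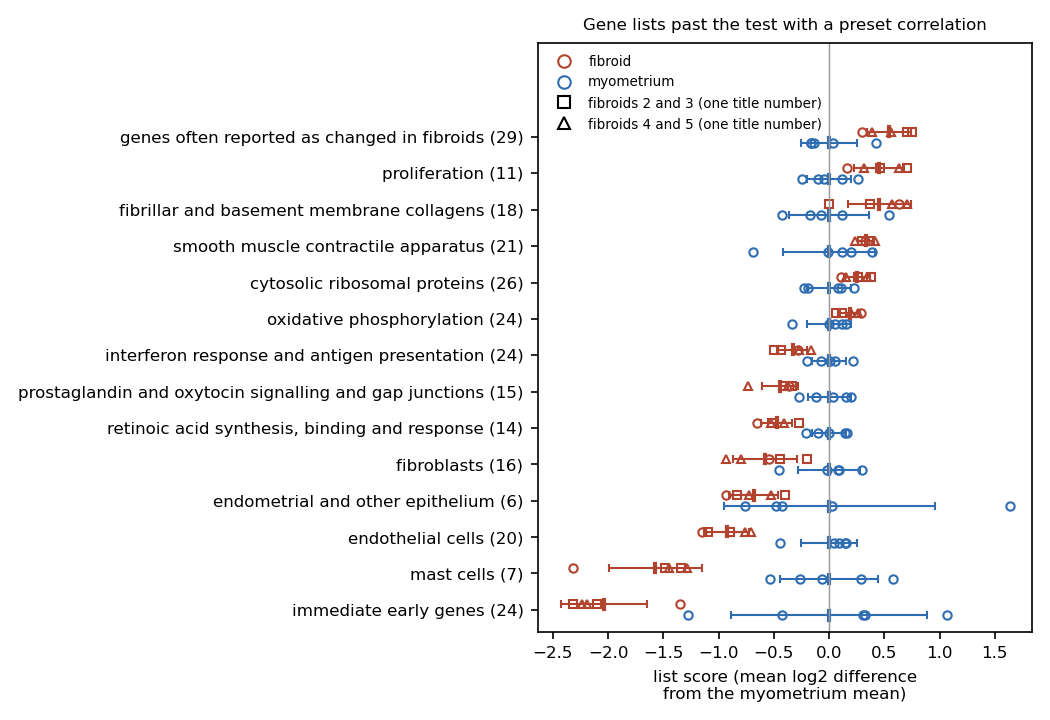
Scores of the 14 gene lists past the test with a preset correlation, 1 point per array (x axis, mean log2 difference of the tested members from the myometrium mean; number of members in parentheses), with group means (thick bars) and SD (thin bars) over 5 fibroid (red) and 5 myometrium (blue) arrays. The fibroids lie below every myometrium array for immediate early genes, endothelial cells, mast cells, retinoic acid genes and prostaglandin and oxytocin genes, while the other lists overlap.

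The remaining 14 lists did not pass. TGF-beta and activin signalling had a median of -0.31 (adjusted p = 0.0553), with the activin subunit INHBA at 1.75 ± 0.43 (SE, adjusted p = 0.0514). Growth factors and their receptors had a median of -0.32 (adjusted p = 0.0634), although PDGFC rose by 1.22 ± 0.23 while VEGFA fell by 1.22 ± 0.27 (SE), the latter past in 5 of the 10 fits without 1 array. Hypoxia and glycolysis genes had a median of -0.03 (adjusted p = 0.0738), with NDRG1 at -1.37 ± 0.22 (SE). Targets of the oestrogen and progesterone receptors had a median of 0.07 (adjusted p = 0.433); in that list CA12 rose by 1.71 ± 0.31 and SGK1 fell by 2.03 ± 0.43 (SE, past in 6 of the 10 fits and lost with same-numbered arrays averaged), and the oestrogen receptor ESR1 was at 0.97 ± 0.32 (SE, adjusted p = 0.159). The insulin-like growth factor axis had a median of -0.05 (adjusted p = 0.433), with the binding protein IGFBP6 at -1.85 ± 0.21 (SE, adjusted p = 0.00139). Wnt signalling genes had a median of -0.27 (adjusted p = 0.798), with SFRP1 and SFRP4 up and CCN5 down. Pericyte markers had a median of -0.30 (adjusted p = 0.0835), stress and heat shock genes -0.22 (adjusted p = 0.0835), HOX genes -0.57 (adjusted p = 0.0914) and lymphatic markers -0.34 (adjusted p = 0.147). Macrophage markers had a median of 0.05 (adjusted p = 0.748) and lymphocyte markers -0.14 (adjusted p = 0.433). Another probe set past the signal filter ran the opposite way for GATA2, FBLN1, CA12 and ESR1.

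The RNA quality measures differed between the tissues in 1 of 2 cases. The log2 ratio of the 3' to the 5' beta-actin control was 0.573 ± 0.324 in fibroid and 0.063 ± 0.209 in myometrium (SD, n = 5 each; exact two-sided permutation test, p = 0.0238, adjusted p = 0.0476). With same-numbered arrays averaged the difference was 0.427 (exact permutation p = 0.0714). The GAPDH ratio was 0.378 ± 0.158 and 0.478 ± 0.170 (SD, n = 5 each; exact permutation p = 0.373). This shift in the beta-actin ratio ran alongside every group change above, and with the ratio as a covariate, an alternative added after the values were seen, 63 genes passed in place of 160. Of the 14 list calls 10 held with it, and 23 of the 48 calls of named genes; GRIA2, PCP4 and FOS were among the 25 lost, at 4.34, 3.39 and -2.96, as was CYBRD1 at -2.14. The covariate also moved MEST to 3.20, PAGE4 to 3.21, NR4A1 to -3.77, TPSAB1 to -3.09 and CPA3 to -2.67, all of which passed. Without fibroids 4 and 5, 33 passed. Between arrays, r across genes ranged from 0.854 to 0.949 within fibroid, from 0.854 to 0.945 within myometrium and from 0.807 to 0.915 between the tissues; genes are not independent replicates. In 1 of the 10 arrays the highest correlation was with an array of the other tissue.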

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

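Of the tests in this part, those with the beta-actin ratio as a covariate and those of vessel content, of handling, of dilution, of admixture and of a sample like the other tissue were chosen after the result was seen; the others were not.

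Immediate early genes were lower in every fibroid. For the count of all passing genes chance is argued against but not excluded. The real split gave 160 and was the 1 split of 26 keeping same-numbered arrays together to give as many, with at most 1 gene in another. That share, 3.85%, is the smallest that 26 splits can give, and the count does not bear on this group alone. RNA integrity read from beta-actin is argued against as the whole cause: with that ratio as a covariate the group difference was -2.07 ± 0.64 (SE, 95% interval -3.59 to -0.542) against -1.97 without it, and the list call at the preset correlation held; whether integrity accounts for a large part cannot be told apart, given that error. Whether a lower vessel content contributes cannot be told apart. The immediate early score minus the endothelial score differed by -1.12, so the group fell further than the endothelial markers did. That difference did not pass (exact permutation p = 0.0635, and p = 0.196 with same-numbered arrays averaged). Handling before preservation could contribute, since the myometrium scores alone spanned 2.34 and no time per sample is given. The biological difference between tumour and muscle remains open and untested beside these, as does donor.

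Endothelial and mast cell markers were lower in every fibroid. RNA integrity read from beta-actin is argued against as the whole cause of either. With that covariate the differences were -1.03 ± 0.21 and -1.98 ± 0.35 (SE), against -0.95 and -1.66 without it. The adjustment is a weak one, since the ratio itself differed between the tissues. Fibroid 1 also had the lowest ratio of its group (0.072, against 0.542 to 0.961) and its lowest score for both marker groups. Whether integrity accounts for a part cannot be told apart. An equal dilution of all cells other than muscle is argued against by the macrophage score alone. It lay 0.918 above the endothelial score in fibroid relative to myometrium (exact permutation p = 0.0159, and p = 0.0179 with same-numbered arrays averaged). The other tested cell types also had negative medians: fibroblasts -0.67, epithelium -0.61, lymphatic cells -0.34, pericytes -0.30 and lymphocytes -0.14. An unequal dilution of cells other than muscle therefore cannot be told apart. Fewer vessels and mast cells in the fibroid samples is a hypothesis that stays open, as does the site of sampling. The 14 list calls as a set do not stand clear of chance: 3 of the 26 splits gave at least 14, and the highest other split gave 15. Each split that gave 15 only exchanged 1 fibroid for 1 myometrium array, so it kept most of the tissue contrast. Yet every other split called lists, 3 in the lowest. The small p-values at the preset correlation therefore overstate the support for single lists.

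In 1 of the 10 arrays the nearest array belonged to the other tissue. A wrong label in general cannot be told apart: over the 167 genes past the threshold without that array, it lay nearer its own group's mean for 61.7%, between the bounds of 25% and 75% set beforehand, while the other arrays reached 67.3% to 97.3%. A mislabelled sample like the 5 arrays of the other tissue is argued against only weakly. The array's mast cell score of -2.31 and endothelial score of -1.15 lay -4.80 and -4.15 standard deviations of prediction from those arrays' mean. Of such samples 95% lie within 2.78. Its immediate early score, at -1.40, lay inside that limit. Both marker groups were chosen after every array of its group, this one included, had been seen to lie beyond the other tissue. The shape of its signal distribution is argued against only so far as quantile normalization removes it. Its highest correlation within its group minus its highest outside it was -0.0291 before that step and -0.0292 after it. The share of probe sets at the floor is not settled by this, since it was highest in that array (23.0%) and next highest in its nearest array (21.7%). Admixture of the other tissue cannot be told apart and a tissue piece unlike the others remains possible. The mast cell and endothelial scores of the array in question were the farthest from the other tissue in its group. But its immediate early score of -1.35 was the nearest, against -2.32 to -2.10 in the rest.

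Of 308 groups of 5 checked for a sample far from the rest, 18 stood out, where chance gives about 15.4; 9 of them lay in fibroid 1 and 4 in myometrium 3. Each value is the gap to the nearest array over the group's range. In fibroid 1 the log2 signals of ADM (0.728), CYBRD1 (0.981) and ZFP36 (0.796) were highest, and those of CPA3 (0.813), DKK3 (0.750) and KIF5C (0.716) lowest. Its scores of immediate early genes (0.775) and stress genes (0.713) were the highest among fibroids and that of mast cells (0.810) the lowest. In myometrium 3, COL6A3 (0.783) and DCX (0.760) were highest and HOXB5 (0.724) and IFI27 (0.728) lowest. ATP5F1A was highest in myometrium 5 (0.720), PCNA in myometrium 4 (0.734) and SGK1 in myometrium 2 (0.805), whose endothelial score was the lowest of its group (0.817). Fibroid 5 had the lowest score of prostaglandin and oxytocin genes (0.823).

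Among the data outside the main measurement, 9 ribosomal RNA control probe sets averaged 0.959 higher in fibroid on the log2 scale, a difference that did not pass. The means were 4.99 ± 1.27 and 4.04 ± 0.33 (SD, n = 5 each, exact permutation p = 0.167, and p = 0.304 with same-numbered arrays averaged). The 4 of 5 fibroids above all myometrium arrays were the 2 same-numbered pairs, while fibroid 1 (3.34) lay below all myometrium arrays. Of 1512 probe sets without a single gene name that passed the signal filter, 19 passed limma's threshold, 8 higher and 11 lower in fibroid.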

How the results depend on the processing

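The alternatives with the beta-actin ratio as a covariate and with a correlation estimated on 10 arrays were added after the values were seen. In place of 160, the genes past the threshold numbered 393 with no block, 96 with same-numbered arrays averaged, 87 with the second array of each pair, 43 with no filter on dim probe sets (11963 genes tested), 95 with no variance trend, 103 without fibroids 2 and 3, 33 without fibroids 4 and 5, 300 with the GAPDH ratio as a covariate and 63 with the beta-actin ratio. Leaving out 1 array gave 91 to 167, with 102 without fibroid 5, 93 without myometrium 1, 100 without myometrium 4 and 91 without myometrium 5. The other settings gave 119 to 206. Of the 14 list calls, 0 held with an estimated correlation on averaged or on 10 arrays, and 6 held with fry. Other settings called 12 to 18 lists, among them 10 to 14 of the 14. The fewest, 10, held with the beta-actin ratio, and 11 held after quantile normalization. With each array left out in turn, 11 of the 14 held every time. The beta-actin difference with averaged arrays was 0.427 and no longer past. Of 48 named genes past the threshold, 8 passed in each of the settings run for single genes (up to 14) and without each array, and 0 reversed there; the GAPDH covariate, the other probe set rules and the plain test were not run for single genes; 34 held with same-numbered arrays averaged, 26 without fibroids 2 and 3, 12 without fibroids 4 and 5, 23 with the beta-actin ratio and 11 with no filter. Lists that did not pass turned direction in the test. That direction comes from the genes' t values, so a median can keep its sign where the test turned. Proteoglycans had medians of 0.28 with no block, 0.21 after quantile normalization and 0.34 after median centring. They were at 0.26 with the floor at the 5th percentile and 0.28 with no trend. Macrophages were at -0.00406 with no block. Both lists also turned with the correlation estimated on 10 arrays, where the medians stay those of the main fit (0.28 and 0.053). Wnt signalling was at -0.30 with the first array of each pair and 0.28 with the filter at the 60th percentile. It was at -0.13 without fibroids 2 and 3 and -0.0585 with the beta-actin ratio. In those last settings matrix proteases were at 0.16 and 0.11, the insulin-like growth factor axis at 0.35 and 0.20, and PDPN at 0.049 and 0.47. Without 1 array the ranges of those that reversed were 0.12 to 0.36 for proteoglycans, -0.040 to 0.16 for receptor targets, -0.14 to 0.21 for macrophages, -0.33 to -0.045 for Wnt signalling, -0.96 to 0.68 for CCL21 and -0.38 to 0.0078 for CCL5. The cause was not tested in these cases, except that dropping the filter adds genes to the adjustment and dropping arrays removes samples. Signal near the floor limits the genes with values there. No paired analysis was possible because the fibroid and myometrium titles share no number.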

Other observations

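Several genes outside the lists also differed. Those of this paragraph were chosen after their values were seen, and no alternative was run for them singly. All of them fell, while 72 of the 160 passing genes rose. The smallest p of all belonged to ANXA1, a phospholipid-binding regulator of inflammation, which fell by 2.23 ± 0.18 (SE, limma adjusted p = 7.6e-05), from 10.46 ± 0.28 to 8.25 ± 0.14 (SD, n = 5 each). The complement proteases C1S and C1R were 2.83-fold and 2.08-fold lower. Of the others, THBD fell by 2.03 ± 0.31, SOX17 fell by 1.93 ± 0.40, RGCC fell by 1.72 ± 0.23, NPR1 fell by 1.69 ± 0.30, EPAS1 fell by 1.65 ± 0.22, SLCO2A1 fell by 1.54 ± 0.34, CAVIN2 fell by 1.52 ± 0.33 and ADGRF5 fell by 1.10 ± 0.24 (SE).

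Both of the next hypotheses came from genes already seen to change, and were tested on other genes with cameraPR, whose p comes from a model across all genes. MEST, COPG2IT1 and PEG3 rose, and imprinted genes might be higher as a class. The 14 others tested had a mean log2 fold change of -0.0152 (95% interval -0.25 to 0.21, adjusted p = 0.742 over both classes) and 0 passed. This argues against a mean rise above 0.21. GRIA2, DCX, KIF5C, CRMP1, NCAM1 and PCP4 rose, and neuronal genes might be higher as a class. The 22 others had a mean of 0.167 and a median of 0.28 (95% interval of the mean -0.07 to 0.40, adjusted p = 0.705) and 0 passed. This argues against a mean rise above 0.40, while a smaller one cannot be told apart. Both intervals treat genes as independent, so they may be too narrow.

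The first principal component held 28.2% of the variance and the second 24.1%. Their relations with technical measures were computed after the values were seen, over all arrays and within tissue, 4 in all, by permutation tests. The second component followed the percent of probe sets at the floor (r = -0.897, rho = -0.806; permutation p = 6e-04 and 0.007, adjusted p = 0.002 and 0.03, n = 10 arrays, of which 4 share numbers), and r was -0.729 without fibroid 1 and myometrium 3. Within tissue, with orders exchanged in each tissue only, r was -0.901 (exact permutation p = 0.00639, adjusted p = 0.00852) and rho -0.65 (p = 0.0761, adjusted p = 0.101). The first component, on which fibroid 1 at -3.61 lay nearer the myometrium arrays (-30.6 to -13.7) than the other fibroids (24.8 to 32.0), followed the beta-actin ratio, whose values overlap between them (r = 0.842, rho = 0.745; permutation p = 0.005 and 0.02, adjusted p = 0.009 and 0.03, n = 10 arrays), and r was 0.741 without fibroids 3 and 5. Within tissue that r was 0.644 and rho 0.3 (exact permutation p = 0.143 and 0.462, before and after adjustment), so the relation over all arrays was not established apart from the tissue. How much of the difference between the tissues goes with RNA quality stays unresolved beyond the covariate fit, in which 63 genes passed.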
